A study of Mus musculus with 11 samples.

How the data were processed

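Gene expression was measured in 11 mammary tumours of female mice aged 12 weeks, 6 from PyMT mice and 5 from PyMT/SIRT6 mice, with 1 array per tumour. PyMT mice carry the polyoma virus middle T oncogene in the mammary gland and develop mammary tumours; the PyMT/SIRT6 mice also carry an extra Sirt6 allele made from a bacterial artificial chromosome, a large genomic clone. Per the labels' protocols, total RNA was amplified to biotinylated cRNA with the Ambion MessageAmp kit and hybridised to Illumina Mouse WG-6 v2.0 arrays at a core facility. Groups were taken from the genotype label of each sample. Replicate numbers follow deposit order only and pair no samples. The labels do not say whether every tumour came from a different mouse, so p-values measure the spread between these samples.

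The deposited values are probe intensities on a linear scale. The background treatment and the normalization applied by the authors are not given in the sources used here. The sorted values of the 11 arrays agreed within 1.08%, so the deposited intensities already shared their quantiles, and no further scaling between arrays was applied. The lowest intensity was 117 on most arrays, the median lay between 157.5 and 157.6 and the highest was 40180.3, so no background subtraction was visible. Without it, the fold change of a dim probe understates the change in RNA. No detection p-value was used here, and the number of arrays limits the precision.

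The table held 45281 probes. In the platform annotation 34885 probes had a single gene symbol, 18 had several and 10378 had none. Of those with a single symbol, 34807 matched a gene identifier of the RefSeq table for assembly GRCm38.p6, and this changed 0 symbols. That table was used only for names and for the order of genes along chromosomes, since the build behind the array's design is not given in the sources used here. For each of 19057 genes the probe with the highest mean over all arrays was kept, and probes without a single symbol stayed as features of their own, giving 29453 features. Intensities were put on the log2 scale. A planned floor of 16 lay below every value and changed 0 of them. The lower 50% of features by mean over all arrays were left out, which removed features with a mean intensity below 158.6 and left 14726, of which 11368 had a gene symbol.

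Genotypes were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend and no covariate. P-values were adjusted by the Benjamini-Hochberg method over all 14726 features, with a threshold of 0.05. Changes are PyMT/SIRT6 minus PyMT on the log2 scale with limma's standard error. Single values such as list means per array were compared by an exact two-sided permutation test over all 462 splits of the arrays, whose smallest possible p is 0.002165.

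Gene lists for metabolism, proliferation, stress, cell types and sample quality were written before the data were examined. They held 864 entries, of which 782 had a probe. The 31 lists with at least 5 tested members were tested by limma's camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The B and plasma cell list had 4 tested members and was not tested. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in a single direction, were run beside it.

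Named genes followed a rule set before the data were examined: Sirt6, then up to 12 genes per direction with the largest change among those passing the threshold, filled with those of smallest unadjusted p, and up to 4 members of each list described. Clone-named and predicted models took no place.

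The gene and list tests were first tested on simulated data for the comparison of PyMT/SIRT6 with PyMT on 14726 features. Of 67 genes changed by 0.5 on the log2 scale 46 were recovered (68.7%), of 67 changed by 1 there were 62 (92.5%), and of 66 changed by 2 all 66. Among 183 calls 9 were unchanged genes, and 0 of 29 unmoved lists were called. The simulation held 200 changed genes, and the adjusted threshold is stricter where fewer genes change. The recovered shares therefore do not carry over to a comparison with few changed genes. The simulated noise was independent between genes and the unmoved lists were random, so the list result does not bear on lists of correlated genes. In the real arrays the estimated correlation was 0.32 for the oxidative phosphorylation list. Other splits of the real arrays gave a median of 10 called lists.

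Alternatives set before the data were examined were other filters on dim features, the mean of a gene's probes, every probe tested separately, centring of arrays, a floor and an offset of 50, eBayes without trend or with robust estimation, array weights, deposit order as a block, adipocyte, lymphocyte or skeletal muscle lists as covariates, and each array left out in turn. Chosen after seeing the data were background subtraction by normexp with an offset of 16, an exact permutation test of list means, and a fit without the 4 arrays with a skeletal muscle list mean above 9. Scripts also used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.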

Results

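Expression was profiled in 6 PyMT tumours and 5 PyMT/SIRT6 tumours, and the design poses a single comparison: tumours with against tumours without the extra Sirt6 allele. SIRT6 is a nuclear NAD-dependent deacylase of chromatin. Correlations between arrays over the tested features ran from 0.9445 to 0.9915, and no arrays were identical. The first principal component held 29.1% of the variance and the second 26%, and neither separated the genotypes (exact permutation p = 0.712 and 0.288).

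Sirt6 itself was higher in every PyMT/SIRT6 tumour than in any PyMT tumour on each of its 3 probes. The brightest probe, ILMN_2684909, went from a geometric mean intensity of 217 (n = 6) to 331 (n = 5), a change of 0.61 ± 0.09 (SE) on the log2 scale or 1.52-fold (exact permutation p = 0.002165, the smallest these arrays can give). The other probes differed by 0.52 ± 0.07 (ILMN_2684910) and 0.26 ± 0.05 (ILMN_2671176), each with the same exact permutation p. Over all tested features limma gave Sirt6 an adjusted p of 0.0574, just above the threshold, and alternatives gave adjusted p from 0.0131 to 0.581. The probe is dim, and with background subtracted by normexp the change was 1.04 (limma adjusted p = 0.0359).

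**Figure D1:**
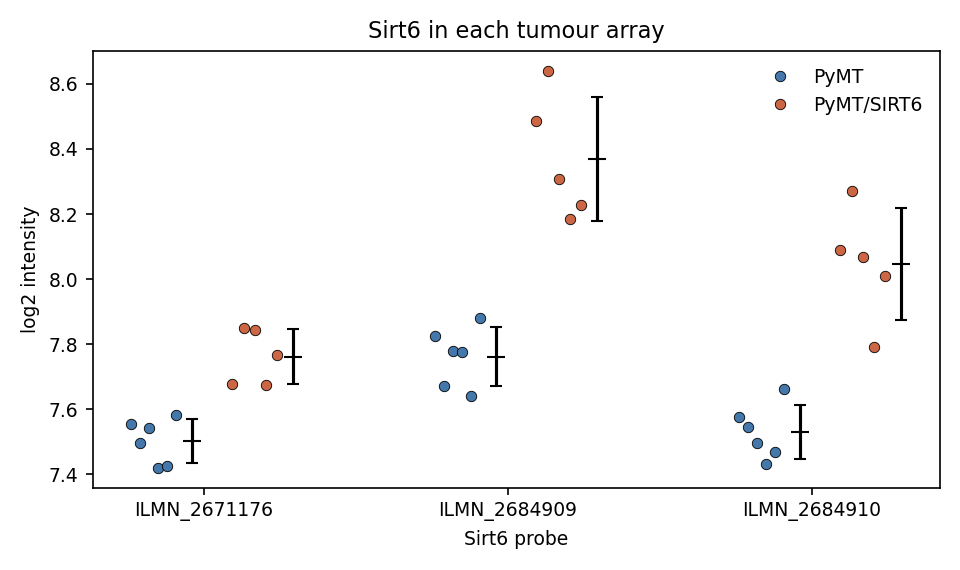
Log2 intensity of the 3 Sirt6 probes in each array, PyMT in blue and PyMT/SIRT6 in orange, with each group's mean and SD beside its points. All 5 PyMT/SIRT6 arrays lie above all 6 PyMT arrays on each probe.

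Tle6 and Tle5 rose in PyMT/SIRT6 tumours. Tle6 and Tle5 belong to the TLE (Groucho) family of transcriptional corepressors, and both lie close to Sirt6 on its chromosome. Their rise alone therefore does not show an action of SIRT6 on them. Tle6 went from a geometric mean intensity of 1006 to 2519.6, 2.50-fold (log2 change 1.32 ± 0.11, limma adjusted p = 3.4e-04), and Tle5 from 1147 to 2380.4, 2.08-fold (1.05 ± 0.14, limma adjusted p = 0.0269). They were the only features of 14726 past the threshold in limma, with 0 lower. At an unadjusted p under 0.05 there were 301 higher and 352 lower features, 653 in all where 736 are expected by chance. Tle6 kept its call when any single array was left out. Tle5 kept it only without PyMT replicate 5, PyMT/SIRT6 replicate 2 or PyMT/SIRT6 replicate 4, so leaving out any other array removed its call, as did testing all features without a filter, the deposit order block, and the lymphocyte or skeletal muscle covariate. Without the 4 arrays with high skeletal muscle markers neither passed, at 1.45 for Tle6 (adjusted p = 0.196) and 1.33 for Tle5 (adjusted p = 0.259), with 7 arrays left.

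The genes next in order did not pass the threshold, and several are neighbours of Sirt6. In the gene order of RefSeq assembly GRCm38.p6, the tested genes Gna11, Tle5, Tle2, Tle6, Sirt6 and Ankrd24 follow each other without a break. Gna11, a G protein alpha subunit, was 0.65 ± 0.11 higher (limma adjusted p = 0.128). Tle2, another member of the TLE family, was 0.74 ± 0.13 higher (limma adjusted p = 0.128). Ankrd24, an ankyrin repeat protein, was 0.34 ± 0.05 higher (limma adjusted p = 0.0903). Gna11 passed with the mean of its probes (0.70) and, on its second probe (0.74), with all probes tested separately, Tle2 without PyMT/SIRT6 replicate 3 (0.83), and Ankrd24 with array weights (0.37), with normexp (0.81) and without PyMT/SIRT6 replicate 2 or 3 (0.37 each), while without the arrays high in skeletal muscle markers Ankrd24 was at 0.19. In each of these 6 genes all 5 PyMT/SIRT6 arrays lay above all 6 PyMT arrays. Over all tested features 43 had this property and 29 the opposite, where chance gives 0.216% in each direction, or 31.9 features. Of the 40 tested genes flanking the 6, 20 on each side, 2 had an unadjusted p under 0.05, and their median change was −0.04.

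**Figure D2:**
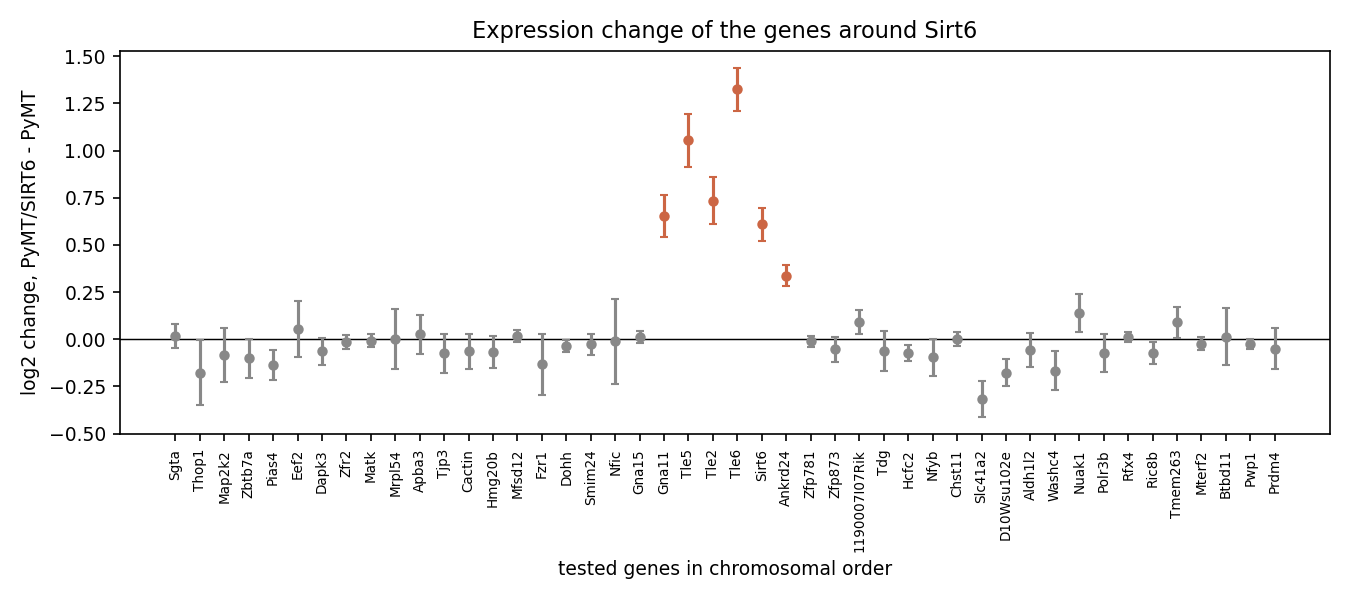
Log2 change (PyMT/SIRT6 minus PyMT) of tested genes in chromosomal order around Sirt6, with bars of 1 limma standard error. The 6 genes from Gna11 to Ankrd24, in orange, lie between 0.34 and 1.32, while the 40 flanking genes in grey have a median of −0.04.

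Elsewhere in the genome the remaining genes named by the rule did not pass either. On the higher side were Tesc, a calcium-binding protein (0.59 ± 0.11, limma adjusted p = 0.183), Msc, a repressor of the basic helix-loop-helix class (0.33 ± 0.07), C1qtnf3, a secreted protein (0.41 ± 0.08), the histone gene H4c11 (0.64 ± 0.13), the TGF-beta-inducible factor Klf10 (0.19 ± 0.04) and the surface protein Plet1 (0.78 ± 0.17). A second probe of Klf10 differed by only 0.01, a second probe of Plet1 by 0.19, and the other probes of C1qtnf3 by 0.25 and 0.09. On the lower side were the lysosomal protease gene Ctsl (−0.15 ± 0.03, limma adjusted p = 0.183), Tmem121 (−0.25 ± 0.05), the acid phosphatase Acpp (−0.17 ± 0.04), the circadian repressor Ciart (−0.13 ± 0.03), Selenbp2 (−0.15 ± 0.04) and the calmodulin-like gene Calml3 (−0.33 ± 0.08). Also lower were the basal keratin Krt15 (−0.18 ± 0.05), Pls1 (−0.14 ± 0.04), the lymphoid transcription factor Ikzf1 (−0.53 ± 0.14), Pde2a (−0.18 ± 0.05), the adhesion molecule Cadm1 (−0.34 ± 0.09) and the translation termination factor Etf1 (−0.37 ± 0.10). The other probes of Acpp differed by 0.00 and 0.01, those of Ciart by −0.04 and −0.11, and those of Ikzf1 ran from −0.30 to 0.04. Several probes on the lower side were dim, the filter limit being 7.309 on the log2 scale. PyMT/SIRT6 means were 7.31 for Ctsl, Ciart and Pls1, 7.27 for Pde2a, 7.23 for Acpp and 7.37 for Tmem121 and Krt15. Ikzf1, Cadm1 and Etf1 were brighter. Small differences of such dim probes need not reflect changed expression.

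Oxidative phosphorylation genes had mostly small positive changes in PyMT/SIRT6 tumours. Of 68 tested members 54 were higher and 14 lower, with a mean change of 0.05, and the list rose by camera (adjusted p = 0.00459) but not with an estimated correlation (adjusted p = 0.868 with an estimated correlation), and the list means did not pass by exact permutation (p = 0.45). The largest evidence per gene was for Uqcr11 of complex III (0.20 ± 0.09), Ndufb2 of complex I (0.18 ± 0.08) and Cox7a2 of complex IV (0.28 ± 0.13), while Uqcrc2 of complex III was lower (−0.21 ± 0.11). In limma, 0 members passed when adjusted over the list alone and 0 over all genes, with 3 at an unadjusted p under 0.05. Skeletal muscle markers were also higher on average, by 0.94, and without the 4 arrays where they were high the oxidative phosphorylation shift was −0.05. That fit kept only replicates 2 and 3 of the PyMT/SIRT6 arrays. Replicate 2 had the lowest oxidative phosphorylation mean of all arrays (11.22). With the skeletal muscle list as a covariate the call held. The call ended without those 4 arrays, without PyMT replicate 2 (shift 0.02) and without PyMT/SIRT6 replicate 3 (0.03), 4 (0.03) or 5 (0.04). It also ended with the lymphocyte covariate (0.03, camera adjusted p = 0.159). The shift was 0.12 without PyMT/SIRT6 replicate 2.

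Glycolysis genes, a class that SIRT6 is known to repress, did not pass by camera (adjusted p = 0.406, and adjusted p = 0.868 with an estimated correlation). Of 17 members 7 were higher and 10 lower, and the list's shift against other genes was −0.03. The pyruvate dehydrogenase kinases Pdk1 and Pdk4 differed by −0.17 ± 0.10 and 0.30 ± 0.20, and Tpi1, a glycolytic enzyme, by −0.27 ± 0.17. Pdk4 was dim, at 7.17 to 7.41 in most arrays of both genotypes. It was higher, at 7.64 to 8.60, only in the 4 arrays high in skeletal muscle markers. The list passed the threshold only without PyMT/SIRT6 replicate 2, at a shift of −0.15 (adjusted p = 0.00883). Genes of the citrate cycle and pyruvate dehydrogenase fell by camera (adjusted p = 0.00752), 15 of 16 members being lower, but not with an estimated correlation (adjusted p = 0.79 with an estimated correlation). Among them Pdha1, a subunit of pyruvate dehydrogenase, was lower by −0.27 ± 0.13 and the succinate-CoA ligase subunit Suclg2 by −0.22 ± 0.11, and in limma 0 members passed over the list alone or over all genes.

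Basal and myoepithelial markers had mostly negative changes in PyMT/SIRT6 tumours and milk genes mostly positive ones. Of 13 basal markers 11 were lower, and the list fell by camera (adjusted p = 7.8e-04; adjusted p = 0.121 with an estimated correlation). The smooth muscle actin gene Acta2 was 0.505-fold of its level in PyMT tumours (−0.99 ± 0.37), Krt5 changed by −0.36 ± 0.14, and the hemidesmosome collagen gene Col17a1 by −0.41 ± 0.16. In limma 1 member, Krt15, was past the threshold when adjusted over the list alone (adjusted p = 0.021) and 0 over all genes. The Krt15 probe was dim, at a mean of 7.37 in PyMT/SIRT6 tumours. The list mean was 8.93 ± 0.16 (SD, n = 6) in PyMT and 8.68 ± 0.05 (SD, n = 5) in PyMT/SIRT6 tumours, below the PyMT mean in all 5 (exact permutation p = 0.0108, adjusted 0.335). Of 15 milk and secretory genes 10 were higher, and the list rose by camera (adjusted p = 0.00459; adjusted p = 0.79 with an estimated correlation; exact permutation p = 0.126 for the list means). The lactose synthase component Lalba was 1.84-fold higher (0.88 ± 0.21) and in limma the only member past the threshold when adjusted over the list alone (adjusted p = 0.0152), with 0 over all genes. Beta-casein, Csn2, was 5.56-fold higher (2.47 ± 0.90), the folate receptor gene Folr1 differed by 0.57 ± 0.18, and Mfge8, a milk fat globule protein, was lower (−0.29 ± 0.11). Csn2 overlapped between the genotypes, at 7.23 to 12.46 in PyMT and 10.08 to 13.68 in PyMT/SIRT6 arrays, with PyMT replicate 1 the highest of its group. The Mfge8 means of 14.92 in PyMT and 14.62 in PyMT/SIRT6 tumours lie near the top of the scale, which limits what its change shows.

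Immune and stromal markers gave camera calls of the same kind. T and NK cell genes rose (10 of 10 higher, mean 0.14, adjusted p = 6.9e-05; adjusted p = 0.446 with an estimated correlation), with Cd2 (0.10 ± 0.03), the cytotoxic granule gene Nkg7 (0.29 ± 0.11) and the T cell receptor component Cd3d (0.26 ± 0.12) leading. Cd2 was the only member past the threshold when adjusted over the list alone (limma adjusted p = 0.0434), with 0 over all genes. Its probe lay near the filter limit of 7.309, at a mean of 7.30 in PyMT and 7.41 in PyMT/SIRT6 tumours. Cd3d was also dim, at 7.51 and 7.78. Macrophage genes rose (17 of 19 higher, adjusted p = 7.8e-04; adjusted p = 0.79 with an estimated correlation), led by Ms4a7 (0.32 ± 0.14) and Cd14 (0.32 ± 0.18). Without the 4 arrays high in skeletal muscle markers the macrophage shift was −0.01, and with the lymphocyte covariate it was 0.09 (adjusted p = 0.134). Fibroblast and matrix genes rose (18 of 22 higher, adjusted p = 0.0266; adjusted p = 0.868 with an estimated correlation), with the collagen Col5a1 at 0.25 ± 0.16 and the proteoglycan Lum at 0.38 ± 0.25, but the shift turned to −0.11 with the lymphocyte covariate and was 0.01 without PyMT/SIRT6 replicate 4. Interferon response genes fell (24 of 27 lower, adjusted p = 8.1e-04; adjusted p = 0.868 with an estimated correlation), among them Ifit2 (−0.33 ± 0.13), Ifit3 (−0.75 ± 0.34) and the deubiquitinase Usp18 (−0.69 ± 0.32). Hypoxia genes fell (15 of 18 lower, adjusted p = 0.00752; adjusted p = 0.79 with an estimated correlation), with the stress gene Ndrg1 at −0.35 ± 0.15 and the HIF prolyl hydroxylase Egln3 at −0.51 ± 0.25, while Pfkfb4 was higher (0.18 ± 0.08). In these last 4 lists 0 members passed in limma when adjusted over the list alone, and 0 over all genes.

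Skeletal muscle genes rose by camera (18 of 20 higher, mean 0.94, adjusted p = 7.8e-04; adjusted p = 0.868 with an estimated correlation), but the list mean varied widely within both genotypes, from 7.38 to 11.8. It lay above 9 in PyMT/SIRT6 replicates 1, 4 and 5 and in PyMT replicate 5. The fast muscle myosin light chain Mylpf differed by 1.62 ± 1.28 and the muscle enolase Eno3 by 1.17 ± 0.96. The genotypes' list means did not differ beyond this spread (exact permutation p = 0.398).

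In all, 10 of 31 lists passed by camera, 6 up and 4 down. With an estimated correlation 0 passed after adjustment and 2 had an unadjusted p under 0.05, the basal list (p = 0.00391) and the T and NK cell list (p = 0.0288). Fry gave 0 after adjustment and 2 unadjusted, and exact permutation of the list means 0 and 1. The 21 lists not called by camera had adjusted p from 0.0567 for the mitosis list to 0.964, and among them were luminal epithelium (0.0749), mitochondrial ribosome (0.0749), DNA repair (0.147), S phase (0.164), fatty acid synthesis (0.164), endothelium (0.189), fatty acid oxidation (0.326) and cytosolic ribosome (0.397). Cholesterol synthesis (0.406), p53 targets (0.415), polycomb complexes (0.43), neutrophils (0.458), adipocytes (0.458), erythroid cells and blood (0.677) and epithelial-mesenchymal transition (0.706) did not pass either. The other sirtuins (0.964), heat shock and immediate early genes (0.964), targets of NF-kB (0.964) and the preset list of Sirt6 neighbours (0.964) had the highest adjusted p. For the last pair the mean change was below 0 while camera's direction was up. Of that preset neighbour list only Ankrd24 lies in the run of 6 genes.

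Most of these list calls depended on single settings or arrays. With the lymphocyte lists as covariate 3 of the 10 kept their camera call, the T and NK cell list not being testable there: the hypoxia list (shift −0.01, adjusted p = 0.412) and the milk list (0.37, adjusted p = 0.0838) no longer passed and the skeletal muscle list turned to −0.21. Without the 4 arrays high in skeletal muscle markers the citrate cycle list (−0.05) and the interferon list (−0.09) no longer passed, and the skeletal muscle list turned to −0.42 (adjusted p = 2.0e-04). The fibroblast call also ended with array weights (shift 0.06, adjusted p = 0.105), with no filter (0.08, adjusted p = 0.143), with the lower 25% of features left out (0.09, adjusted p = 0.0793) and with the skeletal muscle covariate (0.05, adjusted p = 0.217). The hypoxia call ended with array weights (−0.09, adjusted p = 0.066) and with the lower 75% of features left out (−0.12, adjusted p = 0.198), and the citrate cycle call with all probes tested separately (−0.07, adjusted p = 0.0579). Leaving out 1 array ended the call of the citrate cycle list (from a shift of −0.11 to −0.08 without PyMT/SIRT6 replicate 1), of the interferon response list (from −0.21 to −0.10 without PyMT/SIRT6 replicate 2 and −0.13 without 4) and of the milk list (from 0.43 to 0.28 without PyMT replicate 3 and 0.30 without PyMT/SIRT6 replicate 3). Without PyMT/SIRT6 replicate 5 it ended for the macrophage list (from 0.15 to 0.10) and the skeletal muscle list (from 0.94 to 0.41). The hypoxia list went from −0.11 to −0.08 without PyMT replicate 1, −0.06 without PyMT replicate 3 and −0.09 without PyMT/SIRT6 replicate 3, none of which passed. The fibroblast and matrix list went from 0.09 to 0.05, 0.06 and 0.08 without PyMT replicates 1, 3 and 6, and to 0.07, 0.01 and 0.08 without PyMT/SIRT6 replicates 3, 4 and 5, none of which passed. Leaving out other arrays enlarged the shift, to −0.38 for the interferon response list without PyMT/SIRT6 replicate 3, 0.19 for the fibroblast and matrix list without PyMT/SIRT6 replicate 1 and 1.67 for the skeletal muscle list without PyMT replicate 5. The basal list and the T and NK cell list kept their call in every camera setting with the preset correlation in which they were tested. Of the lists not called, the mitosis list passed in 12 alternatives, each time lower. The mitochondrial ribosome list passed as higher in 9 but as lower (shift −0.11, camera adjusted p = 0.00502) without the 4 arrays high in skeletal muscle markers. That fit kept only replicates 2 and 3 of the PyMT/SIRT6 arrays, and replicate 2 had the lowest mitochondrial ribosome mean of all arrays (9.91). The luminal epithelium and fatty acid synthesis lists passed as lower in 5 alternatives each, and the S phase and DNA repair lists as lower in 4 each. Cytosolic ribosome passed as higher in 3, and some other lists newly passed in fewer.

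**Figure D3:**
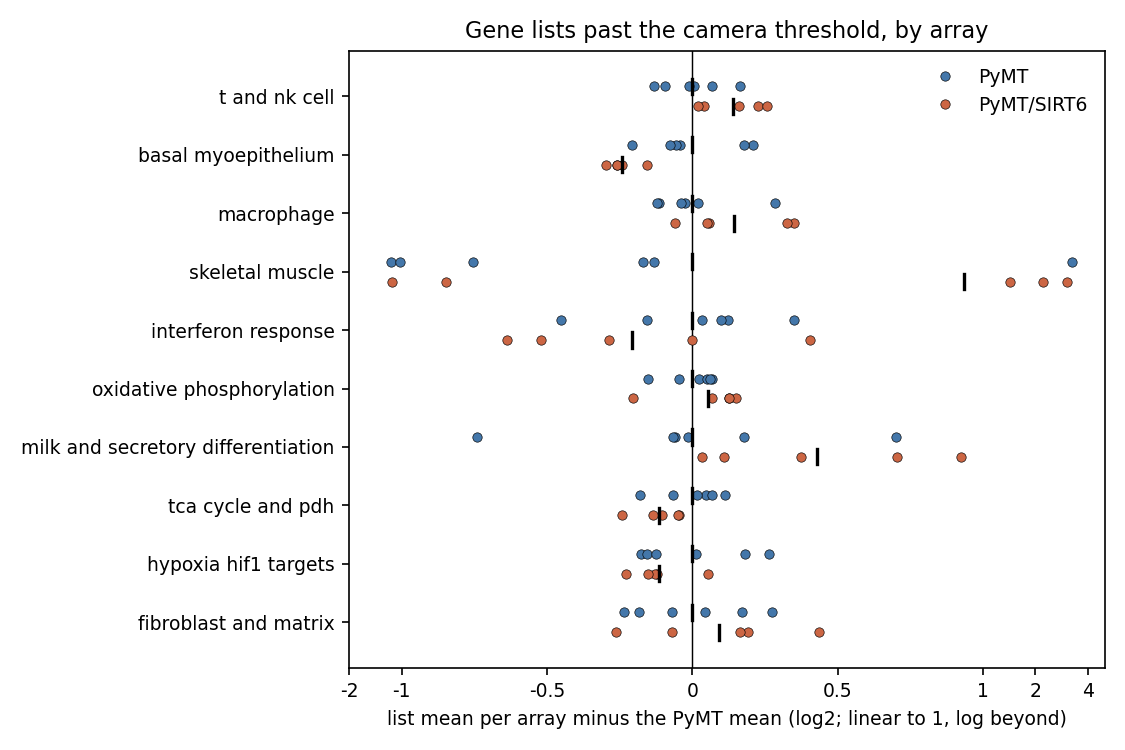
Mean log2 intensity of each list past the camera threshold, per array, minus the mean of the PyMT arrays, with PyMT in blue, PyMT/SIRT6 in orange and group means as black bars. The axis is linear to 1 and logarithmic beyond. The genotypes overlap in each of the 10 lists.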

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

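Of 110 groups of arrays examined, 9 held an array far from the others of its genotype, and chance alone picks out about 1 in 20 groups. The other splits and the muscle covariate test were set before their results were seen; the fit without the arrays high in muscle markers was chosen afterwards.

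The skeletal muscle list mean of PyMT replicate 5 was 11.778, while the other PyMT arrays lay between 7.385 and 8.408. Together with PyMT/SIRT6 replicates 1, 4 and 5 it marks 4 tumours with abundant muscle transcripts, and skeletal muscle carried with the tumour is a candidate source. With the muscle list as a covariate, 8 of the 10 lists kept their camera call and direction, whereas without the 4 arrays 5 did. Other splits of the arrays gave a median of 10 called lists, so keeping a call does not settle its cause. The muscle list could not be tested with itself as covariate, and the fit without the arrays left only 2 PyMT/SIRT6 tumours, so how much muscle adds to these calls cannot be told apart from the loss of arrays. With the lymphocyte lists as covariate only 3 of the 10 lists kept their call, and the T and NK cell list could not be tested there. That list is part of the covariate, and its mean was above the PyMT mean in all 5 PyMT/SIRT6 arrays (exact permutation p = 0.0584). Adjusting for it can therefore also remove genotype differences, so this setting decides nothing. Lymphocyte content is not excluded as a source of the calls. Chance cannot be excluded for the list calls either: 51 of 100 splits of the arrays gave at least as many lists as the real 10, with up to 20 in another split.

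The same splits bear on the metabolic lists. For the oxidative phosphorylation list 39 of 100 splits gave a camera p as small as the real 0.00103, the smallest other being 3.5e-12, and for the glycolysis list 74 of 100 gave a p as small as 0.275, the smallest other being 4.3e-14. Chance is not excluded for either.

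The oxidative phosphorylation list mean of PyMT/SIRT6 replicate 2 was 11.216, below the other PyMT/SIRT6 arrays at 11.486 to 11.57. In the same array the mitochondrial ribosome list mean was 9.91, against 10.317 to 10.376 in the others, and the heat shock and immediate early list mean was 9.396, against 9.006 to 9.113. The heat shock and immediate early list mean was also high in PyMT replicate 1, at 9.341. The macrophage list mean of PyMT replicate 6 was 9.329, above the other PyMT arrays at 8.924 to 9.065. Among named genes, Tesc was low in PyMT replicate 3 (7.459), H4c11 high in PyMT/SIRT6 replicate 1 (10.272), and Selenbp2 high in PyMT/SIRT6 replicate 4 (7.445).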

How the results depend on the processing

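The headline results are Sirt6, the oxidative phosphorylation and glycolysis lists, and the counts of genes and lists. Of the values of the other named genes and lists under alternatives, 3610 kept their direction and side of the threshold, 60 kept the direction and no longer passed, 58 kept it and newly passed, and 76 changed direction. For the headline results these numbers were 138, 7, 12 and 7, counts that stayed close being among the 138, and 17 counts moved further. Signal over background limits dim genes, and in all lists below the values, except for fry, are shifts against other genes on the log2 scale. Quantile normalization was not run, since the values already share their quantiles, and the floor of 16 changed nothing. Where a result changed, the cause was not tested beyond the fewer features or arrays named. The normexp, exact permutation and muscle-array settings were chosen after seeing the data.

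The Sirt6 log2 fold change passed the threshold with no filter (0.61, adjusted p = 0.0361), with the lower 25% (0.61, 0.0403) or lower 75% (0.61, 0.0309) left out, with all probes (0.61, 0.0438), the mean of probes (0.46, 0.0274), robust eBayes (0.61, 0.0355), array weights (0.55, 0.0324), normexp (1.04, 0.0359), and the adipocyte (0.60, 0.0326), lymphocyte (0.71, 0.0131) or muscle covariate (0.65, 0.0271). Left-out arrays gave 0.54 to 0.65, none of them passing.

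The count of genes higher in PyMT/SIRT6, 2, became 6 probes of 4 genes with all probes, 4 with the mean of probes, 4 with array weights, 4 with normexp, 1 with the deposit order block, 0 without arrays high in skeletal muscle and 1 to 3 without a single array. Genes lower in PyMT/SIRT6 numbered 0 in every setting. The lists past the threshold, 10, became 0 with camera with an estimated correlation, 0 with fry, 0 by exact permutation, and 6 to 14 without a single array.

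The oxidative phosphorylation list (0.0542) lost its call with an estimated correlation (0.0542, adjusted p = 0.868), with fry, which tests its mean change and not the shift (0.0527, 0.865), and with the lymphocyte covariate (0.0337, 0.159), and turned without the muscle-rich arrays (−0.0465). The glycolysis list (−0.0349) turned with array weights (0.0139), the lymphocyte covariate (0.0065) and without the muscle-rich arrays (0.0797). Single arrays left out gave 0.0225 to 0.12 for the oxidative phosphorylation list and −0.15 to 0.048 for the glycolysis list.

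With all probes the nfkb targets list was 0.0054 and the sirt6 neighbours list 0.016. With array weights the cholesterol synthesis list was −0.0032, the erythroid and blood list 0.16, the neutrophil list 0.024 and the nfkb targets list 0.0081. With normexp the nfkb targets list was 0.0078 and the sirt6 neighbours list 0.0145. The adipocyte list was 0.034 with the deposit order block and 0.081 with the lower 75% left out, where the heat shock and immediate early list was 0.013. The nfkb targets list was 0.0039 with the lower 25% left out and 0.0013 with no filter. With the mean of probes Dlst was 4e-04, Tnfrsf10b −0.0092, the p53 targets list −0.0199 and the sirt6 neighbours list 0.0153.

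With the lymphocyte covariate Casq1 was −0.0019, Cox6a2 −0.097, Dnajb1 0.0051, Eno3 −0.087 and Loxl1 −0.073, the cell cycle mitosis list 0.077, the cell cycle s phase list 0.083, the dna repair list 0.0248, the erythroid and blood list 0.20, the fibroblast and matrix list −0.11, the heat shock and immediate early list 0.058, the neutrophil list 0.0199, the nfkb targets list 0.0141, the polycomb repressive complexes list 0.0096 and the skeletal muscle list −0.21. With the muscle covariate the cell cycle s phase list was 0.0105, the heat shock and immediate early list 0.0286 and the nfkb targets list 0.0151.

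Without arrays high in skeletal muscle Acaa1a was 0.0363, Cox6a2 −0.23, Eno3 −0.285, Mylpf −0.58, Ogg1 0.0054 and Sirt4 −0.0706. There the skeletal muscle list was −0.42, the cytosolic ribosome list −0.11, the mitochondrial ribosome list −0.11, the endothelium list 0.0202, the heat shock and immediate early list 0.10, the luminal epithelium list 0.0706, the macrophage list −0.01, the nfkb targets list 0.0229, the p53 targets list −0.0512 and the sirt6 neighbours list 0.037.

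Without single arrays the adipocyte list ran from −0.13 to 0.10, the cell cycle s phase list from −0.11 to 0.0032, the cholesterol synthesis list from −0.0186 to 0.0666, the cytosolic ribosome list from −0.0039 to 0.0766, the erythroid and blood list from −0.25 to 0.14, the heat shock and immediate early list from −0.0682 to 0.0358, the neutrophil list from −0.0801 to 0.0437, the nfkb targets list from −0.0151 to 0.0218, the p53 targets list from −0.0305 to 0.0577 and the sirt6 neighbours list from −0.0201 to 0.0193.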

Other observations

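Most tested histone genes had a positive change, though 0 passed the adjusted threshold. Of 48 tested genes for histones H4, H2A, H2B and H3, 44 had a positive change, 15 of them at an unadjusted p under 0.05 in limma, with 0 lower at that level. All 13 tested H4 genes were higher, with a median of 0.25 and 8 at an unadjusted p under 0.05, and their mean per array differed by 0.35 (exact permutation p = 0.0195). Positive changes were also seen in 12 of 15 H2A, 12 of 12 H2B and 7 of 8 H3 genes, with exact permutation p of 0.0606, 0.126 and 0.173 for their means. This group was picked after its values were seen.

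A stretch of milk and salivary genes also stood out when tested genes were read in chromosomal order. In windows of 6 consecutive genes, the highest median change outside the Sirt6 region, 1.21, covered Csn1s1, Csn2, Csn1s2b, Csn3, Smr3a and Prol1, above the median of 0.69 in the Sirt6 window itself. The window was picked as the highest of 11250, so no p is given for its members, and its 4 casein genes belong to the milk list described above. Prol1 differed by 1.74 ± 0.45 and Csn1s1 by 1.62 ± 0.71, and in limma 0 of these 6 genes passed the adjusted threshold. Csn3, at a mean of 15.03 in both genotypes, lies near the top of the scale, so its change of 0.00 decides nothing.

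The remaining paragraphs weigh explanations, and the tests of the genes next to Sirt6 and of the histone genes were chosen after their results had been seen at least in part. Only the test on other splits of the arrays for the number of genes was set beforehand.

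The genes from Gna11 to Ankrd24 were higher together with Sirt6. Hybridisation shared within the TLE family is argued against by Tle1, Tle3 and Tle4, which lie elsewhere and changed by −0.055 on average, and by Gna11, Sirt6 and Ankrd24, which are not TLE genes. A longer linked segment whose genes broadly change expression is argued against by the flanking genes, of which 2 of 40 passed an unadjusted limma p under 0.05. These 2, Slc41a2 (−0.32) and D10Wsu102e (−0.18), are next to each other and both lower. A segment that differs without changing the expression of its genes could not be seen by this test. These 6 were among only 13 genes raised at an unadjusted limma p under 0.001, out of 11358 with a place. The next tested genes on either side, Gna15 and Zfp781, changed by 0.01 and −0.01. Whether the Sirt6 allele may carry extra copies of its neighbours stays open. An unbroken run of 6 with little change in the next tested genes is what such copies would give, but it is the pattern itself. With so few genes raised a second long run was hardly possible, so a comparison with other runs decides nothing. Copy number and an effect of the raised Sirt6 on nearby genes were not measured. By the limit of 5% set beforehand, the splits argue against chance for the number of genes. Of 100 splits, the real one included, 3 gave at least the real 2, though another split gave 4. These 100 splits were drawn from 462 possible ones, so the share is an estimate and does not fully exclude chance. The 2 genes are Tle6 and Tle5, both close to Sirt6, so the count does not show a change elsewhere in the genome.

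For the H4 genes, more cells in S phase and probes that read several near-identical H4 genes are candidate explanations. The S phase list shifted by −0.053 against other genes, opposite to what more cycling cells would give, but its mean per array differed by −0.054 ± 0.098 (SE), so this lies within its error. The median changes of H4 (0.25), H2B (0.24) and H3 (0.25) were alike and that of H2A was 0.08, with several H2A probes near the top of the scale (H2ac10 at 14.5); H4 exceeded the 3 classes by 0.18 (exact permutation p = 0.0281) but H2B and H3 alone by 0.14 (exact permutation p = 0.0714), so an excess of H4 is not shown. Deviations of H4 genes from their group means correlated at 0.60 on average, between the values set for separate and for shared signal, so neither explanation is decided, and an effect of SIRT6 on histone genes stays open and untested.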
